A study of Danio rerio with 30 samples.

How the data were processed

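Small RNA of the spleens of adult AB zebrafish, 100 days after fertilisation, was sequenced in 30 libraries, 5 from controls and 5 from LPS fish at each of 3 incubation temperatures (24, 28 and 32 °C). Per the labels' protocols, embryos and larvae were kept at these temperatures and adults at 28 °C; it is unclear whether the adults meant are the sampled fish or their parents. LPS fish received 2 µl of Pseudomonas aeruginosa LPS at 50 mg/ml into the body cavity, and spleens were taken 12 h later, per the labels' protocols. Whether controls were injected, the sex of the fish and the pairing of samples are not given in the sources used here. Libraries were made from 50 ng of RNA with a NEXTflex v3 small RNA kit, whose adapters carry 4 random bases, and 22 PCR cycles, per the labels' protocols. The submitters' processing notes name bcl2fastq, cutadapt 1.12, FastQC 0.11.5 and DESeq2 1.11.1 without giving each tool's role. The aligner, the counting tool, the genome build and the reference set of miRNAs are not given in the sources used here.

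The values used are the deposited counts, whole numbers of reads per miRNA row and library in one table that the authors deposited. No use of random bases to remove PCR copies is recorded, so counting limits cover counting error alone. Of 8866 rows, 372 carry zebrafish names, 8395 names of other species and 99 names made of a chromosome and a number; 1591 rows had a count in any library. Rows named after other species, and miRNAs spread over several rows, are uncertain because the counting could have divided reads between near-identical sequences. Chromosome names are reported as they stand. Of 60 pairs of libraries checked for shared counts the smallest chi-squared per degree of freedom was 156, where resampling of one library would give about 1. Gene targets were not analysed here.

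Rows were kept by edgeR's filterByExpr on the 6 groups, which left 364 rows (161 zebrafish, 142 of other species and 61 chromosome names, holding 88.9%, 8.41% and 2.65% of the counts); the rows left out held 0.249%. Libraries were scaled with TMM (factors from 0.535 to 1.49), and one model with a mean per group (24 residual degrees of freedom) was fitted with edgeR's robust quasi-likelihood method. Each contrast was tested on that model, with Benjamini-Hochberg adjustment over the rows and a threshold of 0.05. Contrasts were LPS minus control at each temperature and averaged over them; the 3 differences between temperatures within controls and within LPS fish; a joint test of temperature averaged over treatments; and a joint test of the interaction with its 3 pairwise differences. The common biological coefficient of variation was 1.79, and its median over the 100 most abundant rows was 1.01. Of the tested rows 76 had counts in all 30 libraries, 95 in fewer than 15, and 23 had over 50% of their CPM in 1 library. CPM are counts scaled to a common total after TMM, log2 differences carry standard errors from the fit, and a count of 0 was given an upper limit of 3 counts. Library totals and rows detected were compared by permutation (100000 draws), adjusted over 3 pairs.

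Fixed lists of miRNA families were written before the data were examined. They were inflammation-induced (miR-146, 155, 21, 132, 212, 147, 221, 222), teleost antiviral (miR-462, 731), leukocyte (miR-142, 223, 150, 181, 155), red cell and thrombocyte (miR-144, 451, 486), and vascular and stromal (miR-126, 143, 145, 199, 214). Tissue lists were striated muscle (miR-1, 133, 206, 499), liver (miR-122), pancreas (miR-216, 217, 375, 7), gut and epithelium (miR-192, 194, 200, 429, 141, 203, 205), neural and sensory (miR-9, 124, 138, 219, 96, 182, 183) and gonad and embryo (miR-430, 202). The others were let-7 and its companions (let-7, miR-98, 99, 100, 125), miR-17-92 (miR-17, 18, 19, 20, 92, 25, 93, 106, 363), hypoxia and stress (miR-210, 34, 24, 27, 23) and epigenetic (miR-29, 148, 152, 101, 26). miR-155 belongs to 2 lists. The 13 lists with 3 or more tested rows were tested with limma's camera at a preset correlation of 0.01 in 13 contrasts, 169 tests adjusted together, and again with the correlation estimated from the data; liver and gonad, with 1 row each, are given by row. Counts of members are given adjusted over all rows and over the list alone.

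The miRNAs named were chosen by a rule written before the data were examined. Among called rows with a mean of 10 CPM or more, these are the 10 higher and 10 lower with the smallest p, or all where 20 or fewer were called. Where fewer than 5 were called, the 5 smallest p are added as not passing, and each list adds its 4 smallest p. Rows named outside it, such as miR-92a-3p, miR-150 and miR-30b, were chosen after their values were seen.

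The alternatives chosen before the data were examined were DESeq2, limma voom with library weights, RLE scaling, no or a stricter low-count filter (10 counts in 15 libraries), a test against a log2 difference of 1, only the groups compared, the replicate number as a block, rows summed per mature name and each library left out in turn. Added after seeing the data were the log2 library total as a covariate, thinning to the smallest total, leaving out the 4 deepest libraries, zebrafish rows alone, total-count scaling and the 3 temperature contrasts averaged over treatments. The edgeR contrasts of LPS at 28 °C, LPS averaged over temperature and 32 against 24 °C averaged over treatment were tested on simulated data with known changes of 4- and 16-fold. In the simulated LPS contrasts at 28 °C and averaged (347 rows) 1 of 157 and 8 of 159 unchanged rows were called. In that of 32 against 24 °C (339 rows) 8 of 152 were. Beside these, 5 and 23 rows changed 4- and 16-fold were called at 28 °C, 33 and 79 averaged, and 18 and 62 for 32 against 24 °C. The share of false calls among all calls thus lay above 0.05 in the latter 2 contrasts, in simulated data where most rows were changed. Of the changed rows called, 0 had the wrong sign. R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9 were used.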

Results

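MicroRNAs (miRNAs), short RNAs that repress matching messenger RNAs, were counted in the spleen, the blood-filtering lymphoid organ, of adult zebrafish of the AB laboratory strain at an age of 100 days. The fish had developed at an incubation temperature of 24, 28 or 32 °C. At each temperature 5 samples came from control fish and 5 from fish killed 12 h after an injection into the body cavity of lipopolysaccharide (LPS), the outer-membrane component of Gram-negative bacteria that starts an innate immune response. The 30 libraries in 6 groups address whether incubation temperature leaves a difference in the adult spleen, and whether the response to LPS depends on it. The labels do not say that replicates are separate fish, so p-values measure only the spread between these samples.

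A few miRNAs made up most of each library, its 10 most abundant rows holding 70.2 to 85.0% of the counts. The shares that follow pool all libraries, so the deepest libraries weigh most. let-7a, of the let-7 family that marks late development and differentiation, held 27.5% of all counts. miR-92a-3p, of the proliferation-linked miR-17-92 group, held 12.9%, and miR-21, which rises in inflamed tissue, held 10.1%. The 20 most abundant rows held 82.6%. Total counts ran from 199431 to 7584818 per library (median 695337), so a count of 0 allows up to 0.396 CPM (counts scaled to library size) in the deepest library and 15.0 in the shallowest. Median totals were 352754 at 24 °C, 697494 at 28 °C and 1066364 at 32 °C (n = 10 each). The 32 °C libraries held 3.33-fold more counts than the 24 °C libraries (ratio of geometric means, two-sided permutation test, p = 0.00612, adjusted p = 0.0184 over 3 pairs) and 2.03-fold more than the 28 °C libraries (p = 0.117, adjusted p = 0.117). For 24 against 28 °C p was 0.0890 (adjusted p = 0.117). Thinned to an equal total of 199431 counts, the libraries showed 263 ± 46.8, 249 ± 63.6 and 346 ± 85.8 rows with counts at 24, 28 and 32 °C (SD, n = 10 each), and 32 °C differed from both other temperatures (adjusted p = 0.0210 each). Libraries correlated with their own group at a mean r of 0.683 and with other groups at 0.657 (log2 CPM across rows, which are not independent replicates). Names without a species prefix below are zebrafish rows; a prefix such as hsa (human), ssa, ccr, oni, ola, gmo or hhi marks a row named after another species, whose assignment is uncertain.

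**Figure D1:**
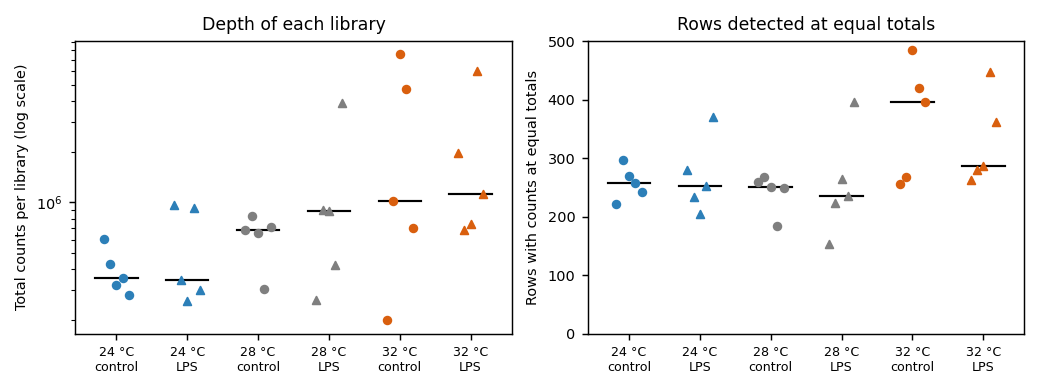
Total counts per library (left, log scale) and rows with counts after thinning to an equal total (right) for the 6 groups of 5 libraries; circles are controls, triangles LPS fish and horizontal bars medians. Totals span 199431 to 7584818, and the 4 deepest libraries are 3 from 32 °C and 1 from 28 °C.

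Libraries from fish incubated at 32 °C had higher CPM of several immune, vascular and developmental-timing miRNAs than those at 24 °C. They also held 3.33-fold more counts, and yield and temperature cannot be told apart here. miR-146a, which NF-κB induces and which represses Toll-like receptor signalling, averaged 1271 ± 706 CPM at 24 °C, 2829.8 ± 1349.8 at 28 °C and 16491 ± 28642 at 32 °C (SD, n = 10 each). miR-143, abundant in smooth muscle and stroma, averaged 6724 ± 3766, 14286 ± 6069 and 49000 ± 66348 CPM. miR-16b, of a family that represses cell-cycle genes, averaged 1660.1 ± 649, 3468 ± 2169 and 12733 ± 14499 CPM, and let-7f averaged 22027 ± 13475, 30996 ± 9748 and 68260 ± 31336 CPM. The log2 difference between 32 and 24 °C was 3.57 ± 0.61 (SE) for miR-146a, 2.86 ± 0.47 for miR-143, 2.93 ± 0.54 for miR-16b and 1.72 ± 0.31 for let-7f, with adjusted p from 0.000159 to 0.000287 (edgeR). For miR-143 and let-7f 10 of the 10 libraries at 32 °C lay above the 24 °C median, and for miR-146a and miR-16b 9 of 10 did. Replicate 5 of the 32 °C LPS fish held 94431 CPM of miR-146a, without which the 32 °C mean was 7831.3 ± 8900.8 (n = 9) and the log2 difference 2.37. Without replicate 7 of the 32 °C controls, at 220449 CPM, miR-143 averaged 29951 ± 29491 (1.74). Without the highest library miR-16b had a difference of 2.13 and let-7f of 1.43 (replicate 5 of the 32 °C LPS fish and replicate 7 of the 32 °C controls). These 4 calls were lost under 1 of 42 alternatives, the total count of each library as a covariate. There the values were 1.78 (miR-146a), 1.65 (miR-143), 1.47 (miR-16b) and 1.13 (let-7f). That alternative is the one that adjusts for library totals, and 30 of the others left out 1 library each.

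The joint test of any temperature difference, averaged over controls and LPS fish, passed for 67 of 364 rows (118 at an unadjusted p under 0.05, 18.2 by chance). Of these, 53 were higher and 14 lower at 32 than at 24 °C, and 39 carried a zebrafish name. Between 32 and 24 °C 60 rows passed, 51 higher and 9 lower, and 54 of them were among the 67. Between 32 and 28 °C 10 passed, and between 24 and 28 °C 0 (edgeR, 55 at an unadjusted p under 0.05, 44 called by DESeq2 and 5 by voom). The 3 pairwise contrasts averaged over treatment were added after the data were seen, to give the joint test a direction. The median row itself lay 0.81 (log2) higher at 32 than at 24 °C under TMM scaling, 0.40 under RLE and 0.18 under total-count scaling, so a difference near 0.81 is no larger than that of the median row. For the 76 rows counted in all 30 libraries, the abundant ones, the medians were 0.46, 0.17 and −0.02. The share of higher rows among those called was 85% of 60 with TMM, 78.8% of 52 with RLE and 70.2% of 47 with total counts. The 67 rows split 53 to 14 under all 3 scalings. That split could hardly change, since the rows were called under TMM and their smallest positive difference there was 0.98 (let-7c-5p). The joint count was 21 with DESeq2, 83 with voom, 25 with a stricter count filter, 148 without a filter, 33 at equal totals and 29 with zebrafish rows alone. For 32 against 24 °C the counts were 84 with DESeq2, 103 with voom, 27 with a stricter filter, 37 at equal totals and 27 with zebrafish rows alone. Without the 4 deepest libraries 35 rows passed the joint test and 16 the contrast of 32 and 24 °C, all 16 higher. With the log2 total of each library as a covariate 4 and 1 passed. Leaving out replicate 7 of the 32 °C controls left 42 and 38.

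**Figure D2:**
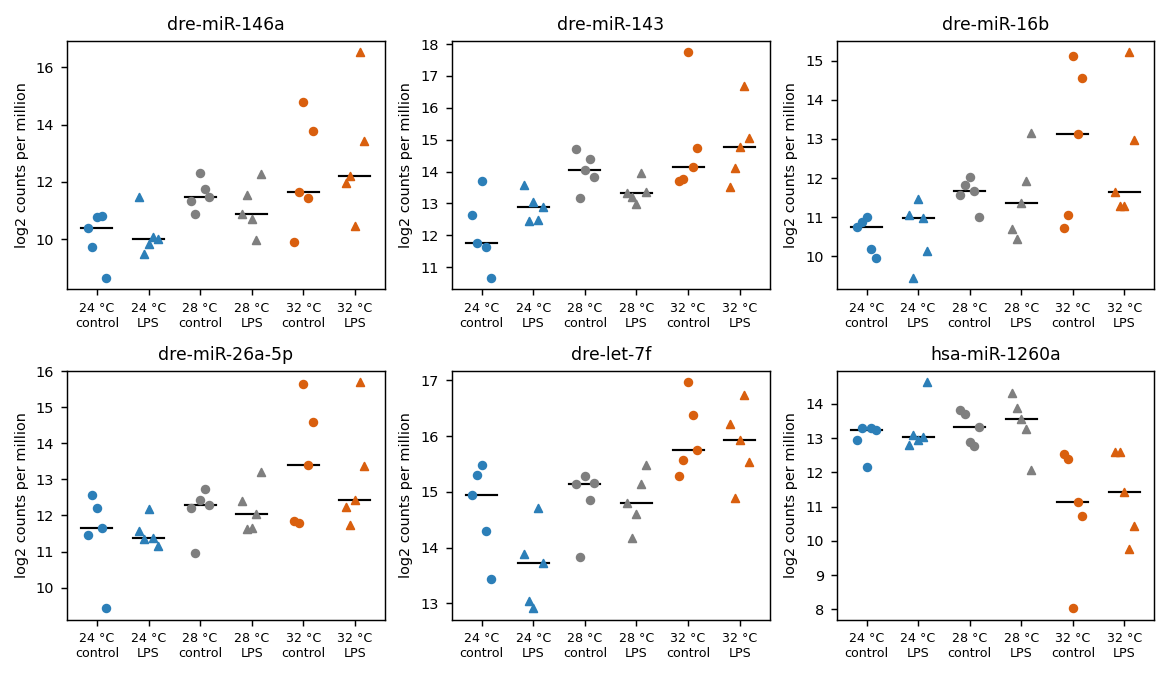
Levels of 6 miRNAs in each library (log2 CPM) by incubation temperature and treatment; circles are controls, triangles LPS fish and horizontal bars medians. miR-146a, miR-143, miR-16b, miR-26a-5p and let-7f rise from 24 to 32 °C, and the row named hsa-miR-1260a falls at 32 °C.

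The median of all rows lay 0.81 higher at 32 than at 24 °C, and 60 of 364 rows passed, 51 of them higher. Most rows of any list can therefore be higher, and such counts alone do not set a list apart. Of the 15 rows of the inflammation-induced list, 14 were higher at 32 than at 24 °C, and 5 passed over all rows (8 adjusted over the list alone). Beside miR-146a, miR-146b averaged 722 ± 414 CPM at 24 °C and 7440.5 ± 10353 at 32 °C (3.37 ± 0.67, adjusted p = 0.000905, 8 of 10 libraries above the 24 °C median). miR-155, made by activated leukocytes, was counted in 1 of 10 libraries at 24 °C, 5 at 28 °C and 7 at 32 °C, and miR-221-5p in 1, 5 and 7. The list stood above other rows (camera with a preset correlation, adjusted p = 0.0492), with adjusted p = 0.973 with an estimated correlation, and lost its call under 13 of 33 alternatives. miR-462, which teleost fish induce with interferon, averaged 1944 ± 797 CPM at 24 °C and 5037.5 ± 4814 at 32 °C (1.38 ± 0.49, adjusted p = 0.0461), and its list had 4 of 4 rows higher with 1 called (1 adjusted over the list alone). In the joint test 0 rows of this list passed. In the leukocyte list 17 of 22 rows were higher and 3 passed (4 adjusted over the list alone), but its median of 0.41 lay below the 0.82 of other rows and its share of the counts was 3.77 ± 1.34% at 24 °C and 2.27 ± 0.628% at 32 °C. They are miR-155, miR-181a-3-3p, counted in 0 of 10 libraries at 24 °C and 4 at 32 °C, and the row named oni-miR-150, of lymphocytes, which fell (−1.28 ± 0.43, adjusted p = 0.0309, 9 of 10 libraries below the 24 °C median). The row oni-miR-150 did not pass the joint test, and its call here was lost under 19 of 41 alternatives, with values from −1.80 to −0.86. The zebrafish row of miR-150 averaged 3133 ± 1378 CPM at 24 °C and 3814 ± 2161 at 32 °C and was not among the calls.

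Among endothelial, smooth-muscle and stromal miRNAs 17 of 24 rows were higher at 32 than at 24 °C and 4 passed (4 adjusted over the list alone), a share near the 60 of 364 over all rows. Next to miR-143, the endothelial miR-126b-3p averaged 1539 ± 867 and 9402 ± 10716 CPM (2.64 ± 0.55, adjusted p = 0.00123) and miR-145-3p, made with miR-143, was 3.15 ± 0.96 higher (adjusted p = 0.0194). Replicate 7 of the 32 °C controls held 17.5% of its counts in this list, against 1.82 to 4.37% in the other 4 controls (group mean with replicate 7 5.65 ± 6.71%, SD, n = 5). The 33 rows of let-7 and its companions miR-99, miR-100 and miR-125 included 12 calls (16 adjusted over the list alone), 10 higher and 2 lower. let-7a rose from 197800 ± 91316 to 399455 ± 121997 CPM (1.05 ± 0.24, adjusted p = 0.00375), against a median of 0.81 for all rows and 0.46 for rows counted in all 30 libraries, and its call was lost with DESeq2, with total-count scaling, with zebrafish rows alone and with the total as covariate. miR-100-5p was 1.99 ± 0.55 higher (adjusted p = 0.0112). The row named gmo-miR-125a-5p fell from 25676 ± 4069 to 11235 ± 6883 CPM (−1.19 ± 0.33, adjusted p = 0.0112), a call lost under 11 of 41 alternatives, with values from −1.69 to −0.82. Of the 8 rows of miRNAs that repress epigenetic enzymes, 8 were higher and 5 passed (5 adjusted over the list alone). Among them miR-26a-5p, whose family represses ezh2, rose by 2.38 ± 0.49 (adjusted p = 0.00123) and miR-26b by 2.62 ± 0.56 (adjusted p = 0.00165). Without the highest library (replicate 5 of the 32 °C LPS fish, and for miR-26b replicate 7 of the 32 °C controls) the differences were 2.39 for miR-146b, 1.80 for miR-126b-3p, 1.61 for miR-26a-5p and 1.51 for miR-26b. The calls of these 4 were lost without the 4 deepest libraries and with the total as covariate.

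Red-cell miRNAs had 5 of 5 rows higher at 32 than at 24 °C, with 2 called (4 adjusted over the list alone). At 32 °C, control replicate 7 held 5.19% of its counts in this list (the other 4 controls at most 1.32%) and LPS replicate 5 held 2.01% (the other 4 at most 0.429%). miR-144-5p averaged 567 ± 461 and 3759 ± 5683 CPM (2.71 ± 0.82, adjusted p = 0.0191), and oni-miR-451b was counted in 0 of 10 libraries at 24 °C and 6 at 32 °C. In the list of hypoxia and stress miRNAs 17 of 20 rows were higher and 4 passed (4 adjusted over the list alone), among them miR-210-5p, a hypoxia-induced miRNA counted in 4 and 8 libraries, and miR-27b-5p, in 1 and 8. In the miR-17-92 list 10 of 18 rows were higher and 2 passed (2 adjusted over the list alone), ccr-miR-18c in 0 and 8 libraries and miR-19b-3p, which did not pass the joint test, in 1 and 6. The list median of 0.61 lay below the 0.81 of other rows, and the list's share of the counts was 23.9 ± 6.10% at 24 °C and 13.5 ± 9.51% at 32 °C. Its abundant member miR-92a-3p averaged 197877 ± 59295 and 152851 ± 111545 CPM and did not pass (−0.42 ± 0.36, adjusted p = 0.436). Rows counted in few libraries at 24 °C met libraries with a median total of 352754, against 1066364 at 32 °C.

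Of the miRNAs of organs next to the spleen, miR-122 rose and few others passed. The liver miRNA miR-122 averaged 1170.5 ± 889 CPM at 24 °C, 1661 ± 2233 at 28 °C and 10511 ± 12546 at 32 °C (3.16 ± 0.73 between 32 and 24 °C, adjusted p = 0.00389, 7 of 10 libraries above the 24 °C median). This call was lost with the total as covariate, and the joint call without replicate 7 of the 32 °C LPS fish, in which miR-122 held 3.86% of the counts. Without that library the difference was 2.09. The acinar miRNA miR-217 was counted in 2 libraries at 24 °C and 7 at 32 °C, the only call among 6 pancreas rows (1 adjusted over the list alone). In the gut and epithelium list 12 of 13 rows were higher and 2 passed (3 adjusted over the list alone), miR-141-3p in 2 and 4 libraries and oni-miR-200a in 2 and 6. Of 3 neural and sensory rows 1 passed (2 adjusted over the list alone), hhi-miR-182 in 2 and 7 libraries. Of 3 striated-muscle rows 0 passed (0 adjusted over the list alone), miR-1 having a value of 3.30 ± 1.62 (adjusted p = 0.154), and the gonad row ssa-miR-202-5p, in 3 libraries at each temperature, did not pass (adjusted p = 0.147). The list tests other than that of the inflammation-induced list had adjusted p of 0.217 or more for 32 against 24 °C.

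The rows that fell at 32 °C mostly carried names of other species or of chromosomes. hsa-miR-1260a averaged 9995 ± 5635 CPM at 24 °C, 11413 ± 4660.5 at 28 °C and 3295 ± 2386 at 32 °C (−1.59 ± 0.43 between 32 and 24 °C, adjusted p = 0.0112, with 10 of 10 libraries below the 24 °C median), and hsa-miR-1260b was −1.56 ± 0.43. hsa-miR-7977 averaged 2464 ± 834, 1883 ± 638 and 731 ± 842 CPM (−1.90 ± 0.52, adjusted p = 0.0112). These 3 calls were lost without replicate 7 of the 32 °C LPS fish, without the 4 deepest libraries, without a count filter and with the total as covariate, and those of hsa-miR-1260a and b also without replicate 8 of the 24 °C or replicate 5 of the 28 °C LPS fish. The values of hsa-miR-1260a ran from −2.01 to −0.93 over the alternatives. The unnamed row chr13_7690 fell from 43344 ± 32271 to 17995 ± 11950 CPM (−1.27 ± 0.39, adjusted p = 0.0194), a call lost under 17 of 41 alternatives, with values from −1.66 to −0.79. For miR-214, a stromal miRNA, the row hsa-miR-214-3p averaged 1494 ± 1078 CPM at 24 °C, 160 ± 155 at 28 °C and 362 ± 350 at 32 °C and passed the joint test (adjusted p = 0.0233), but not the contrasts of 24 and 28 °C (3.29 ± 0.93, adjusted p = 0.0646) or 32 and 24 °C (−1.96 ± 0.89, adjusted p = 0.125). Its joint call was lost under 12 of 41 alternatives.

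Against 28 °C, the usual rearing temperature of zebrafish, 10 rows differed at 32 °C. The 8 higher were miR-146a (2.43 ± 0.58, adjusted p = 0.0154), miR-143 (1.79 ± 0.45, adjusted p = 0.0242), miR-122 (2.80 ± 0.72, adjusted p = 0.0250), let-7f (1.14 ± 0.31, adjusted p = 0.0333), miR-26a-5p, miR-16b, miR-26b and hhi-miR-182, the last counted in 7 and 0 of 10 libraries. hsa-miR-1260a (−1.79 ± 0.43) and hsa-miR-1260b (−1.79 ± 0.43) were lower (adjusted p = 0.0154 each). The calls of miR-146a (0.90 to 2.42 over the alternatives), miR-143, miR-122, let-7f, miR-26a-5p, miR-16b and miR-26b were lost under 21 to 30 of 42 alternatives, those of hsa-miR-1260a and b under 3 of 41 and that of hhi-miR-182 under 10 of 39, among them DESeq2. The median row was 0.83 higher with TMM, 0.63 with RLE and 0.51 with total counts, and 8 of 10 (80%), 1 of 1 (100%) and 1 of 4 (25%) of the rows called under these scalings were higher. The vascular list had 22 of 24 rows higher (adjusted p = 0.0492, and 0.973 with an estimated correlation), 1 called over all rows and 2 adjusted over the list alone, and lost its call under 29 of 33 alternatives. The count of 10 rows was 0 without replicate 2 of the 28 °C controls or replicate 2 of the 28 °C LPS fish and 63 without replicate 8 of the 28 °C LPS fish. It stayed within 1.5 times of 10 without 4 libraries alone, replicate 9 of the 24 °C controls, replicate 1 of the 24 °C, of the 28 °C or of the 32 °C LPS fish (12, 12, 9 and 13). At 24 against 28 °C the smallest adjusted p was 0.0646, shared by let-7c-3p (counted in 0 and 6 libraries), miR-27b-5p (1 and 5), let-7d-3p (0 and 3), miR-30b (2 and 7), chr13_8255, hsa-miR-3150b-5p and hsa-miR-214-3p. The count of 0 became 15 without replicate 5 of the 24 °C controls, 9 without replicate 3 of the 28 °C controls, 7, 16 and 3 without replicates 4, 5 and 8 of the 28 °C LPS fish, 21 without replicate 3 of the 32 °C controls, and 16 and 14 without replicates 2 and 7 of the 32 °C LPS fish.

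Within controls alone, 3 miRNAs were higher at 32 than at 24 °C (81 rows at an unadjusted p under 0.05). miR-143 averaged 5576 ± 4635 and 58652 ± 90619 CPM (SD, n = 5 each; 3.39 ± 0.69, edgeR adjusted p = 0.00548), miR-16b 1562 ± 459 and 14564 ± 15000 (3.22 ± 0.77, adjusted p = 0.0290), and miR-126b-3p 1199.9 ± 1007 and 10039 ± 9637 (3.06 ± 0.79, adjusted p = 0.0493). For miR-143 and miR-126b-3p 5 of 5 libraries and for miR-16b 4 of 5 lay above the 24 °C median. Without replicate 7 of the 32 °C controls miR-143 averaged 18203 ± 6449.3 CPM (n = 4; 1.62), miR-16b 9220.4 ± 10469 (2.48) and miR-126b-3p 5936 ± 3406.5 (2.21), and the 3 calls were lost. In all, the calls were lost under 4 (miR-143, 1.58 to 4.64), 10 (miR-16b, 1.89 to 4.22) and 23 (miR-126b-3p, 1.90 to 3.96) of 43 alternatives. miR-146a and miR-146b had adjusted p = 0.0694 each. The vascular list held 2 of the calls (2 adjusted over the list alone). The inflammation-induced list had 14 of 15 rows higher with 0 called (4 adjusted over the list alone; adjusted p = 0.0492, and 0.973 with an estimated correlation), a list call lost under 19 of 33 alternatives. DESeq2 called 49 rows and voom 78, and 0 passed with the total as covariate, without the 4 deepest libraries or with only these 10 libraries in the fit. The count was 0 without replicate 7 of the 32 °C controls, 1 without replicate 9 of that group or without replicate 3, 8 or 9 of the 24 °C controls, and 30 without replicate 3 of the 32 °C controls. It was 8 to 14 without replicate 5 of the 24 °C controls, replicate 3 of the 28 °C controls, replicates 1 or 5 of the 28 °C LPS fish, replicates 6 or 8 of the 32 °C controls, or replicates 2, 3 or 7 of the 32 °C LPS fish.

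In the same controls 0 rows passed between 32 and 28 °C (edgeR, 75 at an unadjusted p under 0.05, 33 called by DESeq2 and 45 by voom). miR-122 was nearest, with 895 ± 482 CPM at 28 °C and 12914 ± 11407 at 32 °C (3.85 ± 1.07, adjusted p = 0.143), and 4 of 6 pancreas rows passed adjusted over the list alone. Between 24 and 28 °C 0 passed (62 at an unadjusted p under 0.05, 38 by DESeq2, 0 by voom), with miR-125b-2-3p in 0 and 4 of 5 libraries, miR-27b-5p in 0 and 3 and a smallest adjusted p of 0.157. This count of 0 became 6 without replicate 5 of the 24 °C controls or replicates 2 or 7 of the 32 °C LPS fish, 5 without replicate 5 of the 28 °C LPS fish and 7 without replicate 3 of the 32 °C controls.

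Within LPS fish, let-7f and miR-146a were higher at 32 than at 24 °C (67 rows at an unadjusted p under 0.05). let-7f averaged 14308 ± 7628 and 65047 ± 30057 CPM (SD, n = 5 each; 2.18 ± 0.45) and miR-146a 1314 ± 866 and 23099 ± 40030 (4.14 ± 0.89), each with an edgeR adjusted p of 0.00666 and 5 of 5 libraries above the 24 °C median. Without replicate 5 of the 32 °C LPS fish miR-146a averaged 5265.4 ± 4048.9 CPM (n = 4; 2.04) and lost its call, and let-7f averaged 53919 ± 19469 (2.04) and kept it. In all, the calls were lost under 7 (let-7f, 1.51 to 2.54) and 12 (miR-146a, 2.04 to 4.13) of 43 alternatives. let-7a (1.30, adjusted p = 0.0598), let-7g and miR-143 (2.32, adjusted p = 0.0606) did not pass. The let-7 list held 1 call over all rows and 9 adjusted over the list alone. The inflammation-induced list had 14 of 15 rows higher with 1 call (3 adjusted over the list alone; adjusted p = 0.0492, and 0.973 with an estimated correlation), a list call lost under 17 of 33 alternatives. DESeq2 called 21 rows and voom 1. The count was 0 without replicate 5 of the 24 °C controls, replicate 3 of the 24 °C, replicate 2 of the 28 °C or replicate 7 of the 32 °C LPS fish. It was 1 without replicate 8 of the 24 °C, replicates 3 or 5 of the 32 °C LPS fish or replicates 2 or 3 of the 28 °C controls, and 4 without replicate 9 of the 24 °C controls or replicate 6 of the 24 °C LPS fish.

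Between 32 and 28 °C 0 rows passed in LPS fish (edgeR, 35 at an unadjusted p under 0.05, 18 called by DESeq2 and 5 by voom), miR-146a being nearest (3.20 ± 0.85, adjusted p = 0.101). In this contrast 23 of 24 vascular rows were higher (adjusted p = 0.0032, and 0.973 with an estimated correlation), with 0 calls (0 adjusted over the list alone). Between 24 and 28 °C 0 passed (34 at an unadjusted p under 0.05, 23 by DESeq2, 7 by voom). There hsa-miR-214-3p had a value of 4.56 ± 1.40 (adjusted p = 0.400), and the vascular list had 14 of 24 rows higher (adjusted p = 0.0492, and 0.973 with an estimated correlation), a list call lost under 12 of 33 alternatives.

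Controls and LPS fish share no library, so their temperature differences can be compared. Across the 364 rows the 32 minus 24 °C differences of the 2 treatments correlated with Pearson's r = 0.411 and Spearman's rho = 0.504, although rows are not independent replicates. The corresponding values were 0.133 and 0.181 for 32 minus 28 °C and 0.023 and 0.056 for 24 minus 28 °C. With a stricter count filter Pearson's r for 32 minus 24 °C was 0.667. With single libraries left out it ran from 0.243, without replicate 5 of the 32 °C LPS fish, to 0.464. In both treatments the median library total was higher at 32 than at 24 °C, so this correlation does not separate temperature from yield.

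**Figure D3:**
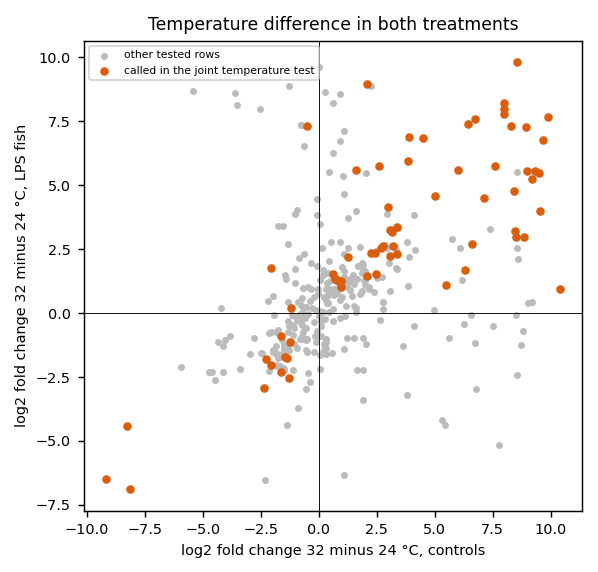
Log2 difference of each of the 364 rows between 32 and 24 °C in controls (horizontal) and in LPS fish (vertical), with the rows that passed the joint temperature test marked. Pearson's r across rows was 0.411.

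No miRNA of the inflammation-induced list passed between LPS fish and controls. Averaged over temperature, 14 of the 15 rows of the inflammation-induced list had positive values with a median of 0.56 (log2) against 0.056 for the other rows, and 0 of them passed (0 adjusted over the list alone). miR-222a-3p averaged 2238 ± 1164 CPM in controls and 3333 ± 2310.2 in LPS fish (SD, n = 15 each; 0.56 ± 0.33, adjusted p = 0.652). miR-21 averaged 72938 ± 35302 and 90915 ± 77294 CPM (0.25 ± 0.27, adjusted p = 0.915), and miR-146a 4754.6 ± 7324.5 and 8973.5 ± 23788. The list test gave an adjusted p of 0.0677 with a preset and 0.973 with an estimated correlation, both averaged and at 32 °C, where 14 of 15 rows were positive. At 24 °C 12 rows were positive (adjusted p = 0.141) and at 28 °C 8 (adjusted p = 0.835). Of the interferon-linked miR-462 and miR-731 rows 4 of 4 were positive (adjusted p = 0.334).

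**Figure D4:**
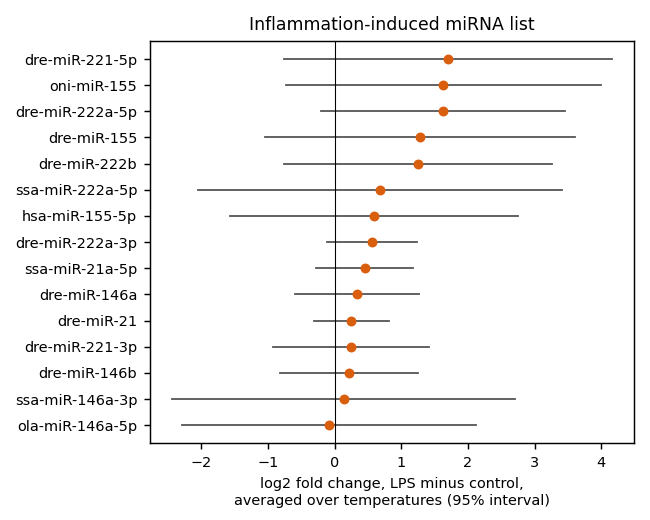
Log2 difference between LPS fish and controls, averaged over the 3 temperatures, for the 15 rows of the inflammation-induced list (points, with 95% intervals). 14 of the points lie above 0 and every interval includes 0.

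In the LPS comparison averaged over temperature 2 rows passed, both lower (edgeR, 38 at an unadjusted p under 0.05, 24 called by DESeq2, 0 by voom). The unnamed row chr4_36463 was counted in 4 of 15 LPS and 9 of 15 control libraries (adjusted p = 0.0202), and 89.2% of its CPM came from 1 library. The row named mmu-miR-3963 was counted in 3 and 9 (adjusted p = 0.0452). Next came hsa-miR-3150b-5p, in 9 and 13 libraries (adjusted p = 0.0641). The calls were lost under 19 (chr4_36463) and 28 (mmu-miR-3963) of 40 alternatives. The count was 0 without replicate 9 of the 24 °C controls, replicates 1, 2 or 6 of the 24 °C LPS fish, replicate 3 of the 28 °C controls, replicates 1, 2, 5 or 8 of the 28 °C LPS fish, replicates 3 or 8 of the 32 °C controls or replicates 1, 2 or 7 of the 32 °C LPS fish. It was 1 without replicate 5 of the 24 °C controls, replicates 3 or 8 of the 24 °C LPS fish, replicates 2 or 5 of the 28 °C controls, replicate 4 of the 28 °C LPS fish, replicate 7 of the 32 °C controls or replicates 3 or 5 of the 32 °C LPS fish, and 4 without replicate 8 of the 24 °C controls. Of the red-cell list 2 of 5 rows were positive, and ccr-miR-144, in 2 LPS and 6 control libraries, passed adjusted over the list alone. Of the neural list miR-183-5p, in 4 and 6 libraries, did so too. In the other lists 0 rows passed on either scale. Of 24 vascular rows 9 were positive, of 22 leukocyte rows 13, of 33 let-7 rows 14, of 18 miR-17-92 rows 12, of 20 hypoxia rows 8 and of 8 epigenetic rows 2.

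At single temperatures 0 rows passed over all rows. Adjusted over the list alone, 2 of 3 muscle and 2 of 3 neural rows passed at 24 °C, 2 epigenetic, 1 red-cell and 1 miR-17-92 row at 28 °C and 0 rows at 32 °C. At 24 °C edgeR gave 44 rows at an unadjusted p under 0.05 and a smallest adjusted p of 0.276, and DESeq2 called 29 and voom 0. The 5 smallest p belonged to ccr-miR-133a-3p (in 0 LPS and 2 control libraries), chr4_36463 (1 and 2), miR-125b-2-3p (3 and 0), miR-363-3p (0 and 2) and miR-206-3p, with 430 ± 917 CPM in controls and 0.712 ± 1.13 in LPS fish (SD, n = 5 each). miR-133 and miR-206 are muscle miRNAs, and control replicate 8 held 0.395% of its counts in the muscle list against at most 0.0343% in the other 4. At 28 °C edgeR gave 48 rows, and DESeq2 called 24 and voom 4. hsa-miR-3150b-5p was counted in 0 of 5 LPS and 5 of 5 control libraries, at 149 ± 103 CPM in the latter (adjusted p = 0.119), and miR-25-5p in 5 of 5 and 0 of 5, at 152 ± 184 CPM in LPS fish. This count of 0 became 3 without replicate 7 of the 32 °C LPS fish. At 32 °C edgeR gave 7 rows, fewer than the 18.2 expected by chance, and DESeq2 called 2 and voom 1. There the islet miRNA miR-375 averaged 3076 ± 1685 CPM in controls and 761 ± 617 in LPS fish (−2.01 ± 0.90, adjusted p = 0.999). Of 6 pancreas rows 0 were higher in LPS fish at 32 °C, and of 13 gut and epithelium rows 1 (adjusted p = 0.0492 each, and 0.973 each with an estimated correlation), list calls lost under 17 and 21 of 33 alternatives. At 24 and 28 °C 5 of the 6 pancreas rows were instead higher in LPS fish (adjusted p = 0.212 and 0.334), and of the 13 gut and epithelium rows 8 and 4 were higher. The pancreas list held 0.347 ± 0.160% of the counts of these controls and 0.108 ± 0.0839% of those of the LPS fish, and the gut list 0.371 ± 0.572% and 0.114 ± 0.138%. In controls and LPS fish the pancreas list held 0.0998 ± 0.0744% and 0.441 ± 0.443% at 24 °C and 0.0834 ± 0.0478% and 0.159 ± 0.0785% at 28 °C.

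The LPS response was compared between temperatures by an interaction test, in which 0 rows passed (edgeR, 44 at an unadjusted p under 0.05, smallest adjusted p = 0.303, 0 called by DESeq2 and 2 by voom). miR-206-3p had the smallest p (0.00215), followed by ssa-miR-30d-2-3p, miR-200a-3p and mmu-miR-3963. The LPS effect on miR-375 differed between 32 and 24 °C by −4.14 ± 1.28 (adjusted p = 0.391), with 826 ± 577 CPM in controls and 3602.5 ± 3850.4 in LPS fish at 24 °C. Adjusted over the list alone, 2 of 3 muscle rows, 1 pancreas row and 1 gut row passed. On simulated counts with these library sizes and spreads, the LPS contrast at 28 °C recovered 5.32% of 4-fold and 24.0% of 16-fold changes among 347 rows. Among the 100 most abundant rows it recovered 14.3% and 59.4%. In that simulation 94 and 96 rows were changed and 157 were not. The adjustment is stricter where few rows change, and such a sparse response was not simulated. The contrast averaged over temperature recovered 34.7% and 84.9% (60.7% and 100% among the 100 most abundant rows). That of 32 and 24 °C averaged over treatment recovered 19.4% and 66.0% among 339 rows (35.7% and 96.9%). The interaction was not simulated. The median standard errors of its pairwise differences, 2.70 to 2.77, exceeded the 2.03 of the LPS contrast at 28 °C.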

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

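Of the tests described here, those of counting depth, yield and few-library rows were chosen after the results they concern were seen, and that of other organs was written before its slopes but after the shares of these lists were seen. Values were singled out in each group of 5 libraries by Dixon's rule. The gap to the nearest of the others, as a part of the whole range, had to pass its 95% critical value. Chance does this in about 1 of 20 groups of normally distributed values. In all 43 of 229 tests passed, 24 of 108 for library values and list shares and 19 of 121 for miRNA levels. Where the other libraries of a group are all at 0 or at the floor, any higher value passes. The 43 can therefore not be read against the rate of 1 in 20.

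Single libraries were singled out by this rule from the other 4 of their group in the following values, with levels as log2 CPM. Replicate 5 of the 28 °C controls had a log2 total of 18.2 and 184 rows with counts at equal totals. Replicate 8 of the 28 °C LPS fish had 3.39% of its counts in the teleost antiviral list, 0.0139% in the neural and 0.00305% in the gonad list, and log2 CPM of 4.81 (chr4_36463), 1.25 (mmu-miR-3963), 5.40 (ccr-miR-18c), 4.26 (chr13_8255) and 8.75 (hsa-miR-7977). It was the deepest library of its group (3903189 counts), and the other 4 were at 0 or at the floor of 0.89 for chr4_36463, mmu-miR-3963, chr13_8255 and the neural and gonad lists. Replicate 7 of the 32 °C controls had 5.19% in the red-cell, 17.5% in the vascular and 0.00427% in the gonad list, and miR-143 at 17.75. In the 32 °C LPS fish, replicate 2 had 3.59% in the leukocyte list, replicate 5 had 2.01% in the red-cell list, and replicate 7 had 3.86% in the liver and 0.0125% in the gonad list; replicate 9 of the 32 °C controls had 1.37% in the gut list.

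At 24 °C, replicate 5 of the controls had 0.673% in the antiviral list and log2 CPM of 6.70 (mmu-miR-3963) and 14 (gmo-miR-125a-5p). Replicate 8 had 0.395% in the muscle and 0.0227% in the neural list. Replicate 3 had 0.0550% in the gonad list, 12.17 (hsa-miR-7977) and 16.99 (chr13_7690), and replicate 1 had 3.44 (miR-146b). Of the LPS fish, replicate 8 had 0.0333% in the muscle list and 14.63 for both hsa-miR-1260a and hsa-miR-1260b, replicate 2 had 0.0462% in the neural and 0.0747% in the gonad list, and replicate 3 had 0.821% in the epigenetic list, 5.81 (chr4_36463) and 15.94 (chr13_7690). At 28 °C, LPS replicate 4 had 0.438% in the muscle and LPS replicate 1 0.297% in the pancreas list. Control replicate 3 had 0.0136% in the gonad list, control replicate 1 had 0.89 (hsa-miR-214-3p), and control replicate 2 had 2.53 (ccr-miR-18c), 9.75 (hsa-let-7d-3p) and 7.78 (chr3_31903).

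The temperature calls could come from the deeper 32 °C libraries. Thinned to equal totals, the called rows' median difference relative to all rows kept 96.2% of its size (2.69 before and 2.59 after), with 51 of 51 rows keeping their sign. Random thinning leaves expected shares unchanged, so size and sign were bound to be kept and decide nothing. At equal totals 33 rows passed the joint test, against at most 7 in other regroupings, so counting depth alone does not account for these 33. It stays open for called rows that did not pass there, and for the 16 of the 67 with too few counts to be tested at equal totals. A library's yield may reflect more than counting. The slope of the rows' score on the log2 total within the 24 and 28 °C groups gives 14.8% of the difference (−6.11 to 35.8%; r = 0.363, permutation p = 0.0987, n = 20) and within 32 °C 41.9% (12.1 to 71.7%; r = 0.782, permutation p = 0.0200, adjusted p = 0.0400, n = 10; 0.501 without the 2 farthest libraries), where the rows were chosen on that same difference, so yield and temperature cannot be told apart.

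RNA of a neighbouring organ could raise the temperature calls outside the other-organ lists. The slope of their score on the log2 share of these lists gives 3.60% of the difference within the 24 and 28 °C groups (−5.77 to 13.0%; r = 0.207, permutation p = 0.288, n = 20) and 10.5% within 32 °C (−6.04 to 27.1%; r = 0.494, permutation p = 0.146, adjusted p = 0.288, n = 10; 0.539 without the 2 farthest libraries). Both upper bounds lie below 50%. The rows were chosen on that same difference, and a share as small as 0.575% at 24 °C is measured with error, which flattens a slope. These slopes are therefore small but cannot exclude RNA of a neighbouring organ. The rank correlation within 32 °C was 0.661 (permutation p = 0.0484, not adjusted). Such RNA also stays open for the rows of these lists themselves: they gained 0.917 points of the counts between 24 and 32 °C (two-sided permutation test, n = 10 each, p = 0.132), and miR-122 went from 0.135 to 0.966% (permutation p = 0.0165, adjusted p = 0.0247).

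The LPS calls of DESeq2 (29 at 24 °C and 24 at 28 °C) could come from rows counted in few libraries, and an on-off response would look alike in the real grouping. In the 49 other regroupings, which mix LPS and control libraries, DESeq2 called a median of 35 and 26 rows, and 88.8% of these calls had counts in at most 1 of 5 libraries of one group (94.0% and 81.7%, against 52.7% and 46.3% of the rows DESeq2 tested). Each regrouping keeps a part of the LPS contrast, since 5 LPS libraries cannot be divided evenly. Such rows gave as many calls with that contrast reduced; which of the real calls are a response stays open.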

How the results depend on the processing

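The log2-total covariate, thinning, the 4 deepest libraries left out, zebrafish rows alone, total-count scaling and the averaged temperature contrasts were chosen after seeing the data. Of the values of named miRNAs and of the list calls 0 reversed in direction, 3830 were the same, 112 stronger and 616 weaker. Rows called in neither setting count as the same. Of the numbers of calls and the correlations 606 were the same, 75 stronger, 105 weaker and 1 moved. Numbers of calls were compared by size alone, so a change of direction does not show. For averaged 32−28 °C 8 of 10 called rows were higher with TMM and 1 of 4 with total counts. The cause was not tested for the changes below. Depth limits a count of 0 to 0.396 to 15.0 CPM.

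Calls by DESeq2 were 29, 24, 2 and 24 for LPS at 24, 28, 32 °C and averaged; 38, 33 and 49 in controls and 23, 18 and 21 in LPS fish for 24−28, 32−28 and 32−24 °C; 21 for the joint test; and 44 and 36 for averaged 24−28 and 32−28 °C. Calls by voom were 4, 1 and 0 for LPS at 28, 32 °C and averaged; 45 and 78 in controls for 32−28 and 32−24 °C; 7, 5 and 1 in LPS fish; 2 for the interaction; and 5, 55 and 103 for averaged 24−28, 32−28 and 32−24 °C. Without a filter calls were 4 (LPS at 28 °C), 3 and 1 (controls, 24−28 and 32−24 °C), 148 (joint), 2 (interaction), 10 and 5 (averaged 24−28 and 32−28 °C). With a stricter filter they were 0 (LPS averaged), 9 (controls, 32−24 °C), 25 (joint) and 27 (averaged 32−24 °C), and the correlation for 32−24 °C was 0.667. With only the groups compared they were 1 and 0 in controls (32−28 and 32−24 °C) and 1, 1 and 4 in LPS fish; results that use all groups have no such value. With rows summed they were 1 (LPS averaged), 8 (controls, 32−24 °C) and 1 (averaged 24−28 °C). RLE gave 1 (averaged 32−28 °C) and 1 list call, and the estimated correlation 0 list calls.

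With the covariate calls were 1 (LPS averaged), 0 (controls, 32−24 °C), 4 (joint) and 1 (averaged 32−24 °C); thinned 0 (LPS averaged), 33, 5 and 37 (joint, averaged 32−28 and 32−24 °C); without the 4 deepest libraries 0 (LPS averaged), 0 (controls, 32−24 °C), 35, 2 and 16; with zebrafish rows 0 (LPS averaged), 1 and 1 (LPS fish, 32−28 and 32−24 °C), 29, 1 and 27; and with total-count scaling 4 (LPS fish, 32−24 °C) and 4 (averaged 32−28 °C).

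With the replicate number as a block calls were 0 (LPS averaged), 10 (joint), 3 and 32 (averaged 32−28 and 32−24 °C). Same-numbered libraries share only a number: 13 of 43 pairs had deviations correlated above 0.1 (mean 0.064, against −0.008 for other pairs), and 8 of 30 libraries correlated best with their own number, a hint from the data.

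Leaving out each library gave 0 to 0 calls for LPS at 24 and 32 °C, 0 to 3 at 28 °C and 0 to 4 averaged; 0 to 7, 0 to 0 and 0 to 30 in controls for 24−28, 32−28 and 32−24 °C; 0 to 0, 0 to 0 and 0 to 4 in LPS fish; 42 to 97 for the joint test; 0 to 0 for the interaction; 0 to 21, 0 to 63 and 38 to 88 averaged; and 1 to 15 list calls. Correlations ranged from −0.00816 to 0.0759, 0.0453 to 0.236 and 0.243 to 0.464. The joint count was lowest without replicate 7 of the 32 °C controls. Of the 8 list calls 1 was left without replicate 3 of the 24 °C controls, replicate 8 of the 32 °C controls or LPS replicates 1, 3 or 6 at 24 °C, 1 or 2 at 28 °C or 1 at 32 °C. There were 2 to 5 without LPS replicates 2 (24 °C), 5 (28 °C), 5 or 7 (32 °C) or control replicates 2 (28 °C) or 6 (32 °C), 13 without replicate 8 of the 24 °C controls and 15 without replicate 2 of the 32 °C LPS fish.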

Other observations

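The regroupings of the thinned counts, of the fit with the library total and of the inflammation-induced list, were written before their results were seen, and the other regroupings after. Between 24 and 32 °C the let-7 list went from 42.2 ± 11.7% to 52.4 ± 11.8% of the counts (SD, n = 10 each) and the miR-17-92 list from 23.9 ± 6.10% to 13.5 ± 9.51%. The leukocyte list went from 3.77 ± 1.34% to 2.27 ± 0.628%, and the epigenetic list from 0.537 ± 0.244% to 1.75 ± 1.76%. These shares were not tested.

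The libraries were regrouped at random, the real grouping included among 100. The results were not adjusted for their number. The real grouping alone reached its value for 3 results. These were the joint temperature test (67 calls, 1 of 100 as many, highest other 33), the joint test on thinned counts (33 calls, 1 of 100, highest other 7) and the correlation of 32−24 °C differences (0.411, 1 of 100, highest other 0.313). A share of 1 of 100 is the smallest that 100 groupings can give. Without adjustment it makes chance unlikely for each result taken alone but does not exclude it. For 32−24 °C averaged (60 calls, 2 of 100, highest other 60), chosen after seeing the data, and in LPS fish (2 calls, 3 of 100, highest other 2), other regroupings called as many, so chance was not clearly excluded. The count in LPS fish changed without 11 of 30 single libraries, to 0 without replicate 5 of the 24 °C controls. Nor was chance clearly excluded for 32−28 °C averaged (10 calls, 4 of 100, highest other 59), also chosen after seeing the data. Its 10 calls became 0 without replicate 2 of the 28 °C controls or replicate 2 of the 28 °C LPS fish and 1 with RLE. Chance was not excluded for 32−24 °C in controls (3 calls, 6 of 100, highest other 8), LPS averaged (2 calls, 24 of 100, highest other 29), the list tests (8 calls, 13 of 100, highest other 12), the joint test with the library total as covariate (4 calls, 64 of 100, highest other 30), the median of the inflammation-induced list above other rows (0.502, 9 of 100, highest other 0.934) or the correlations for 24−28 °C (0.0226, 49 of 100, highest other 0.288) and 32−28 °C (0.133, 15 of 100, highest other 0.306).

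Where edgeR called 0 rows (the counts at an unadjusted p under 0.05 and by DESeq2 and voom stand with each result above), any regrouping calls as many (100 of 100), so these counts say nothing about chance. The highest other counts were 2, 1 and 59 for LPS at 24, 28 and 32 °C, 2 and 0 for 24−28 and 32−28 °C in controls, 2 and 2 in LPS fish, 33 for the interaction and 23 for averaged 24−28 °C. With DESeq2, 48, 34 and 46 of 50 regroupings called as many rows as LPS at 24 °C (29, highest other 48), at 28 °C (24, highest other 42) and averaged (24, highest other 96). Why some regroupings call several times the real count, as for LPS averaged and 32−28 °C, was not tested.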
